A study of Arabidopsis thaliana with 12 samples.

How the data were processed

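Poly(A) RNA of young Arabidopsis leaves was sequenced in 12 libraries, 3 for each of 4 groups. The groups were the reference accession Col-0 and the mutant npf8.4-1, each sampled at day 0 and at day 2 of nitrogen depletion. Groups and replicate numbers were taken from the sample titles and the genotype and treatment labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The replicates are described in the labels as biological, each a pool of 15 plants. Adjusted p-values measure the spread between these pools.

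The authors deposited 1 table per library with 37242 genes. Per the file headers, each table holds a count of exon reads per gene, and the values are whole numbers that sum to a different total in each library. The authors also deposited a TPM value and an RPKM value per gene in the same tables. TPM and RPKM were computed upstream from the counts and were not tested here, because the count test keeps the depth of each library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and the genome build was TAIR10. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here. Whether reads of overlapping and antisense genes were kept apart, and how reads were shared between close paralogs, is therefore unknown. Of the 37242 genes, 36810 matched the reference gene table by locus name and 36794 of these had the same start and end. Coordinates are those of the deposited tables, counted from 1. Library totals ran from 28761674 to 34282716 reads. A group in which all 3 libraries had 0 reads was given a floor of 3 counts over the group. Ratios with 1 to 3 counts in a group are given with a 95% counting interval. These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

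Counts were tested with the edgeR quasi-likelihood test (R 4.3.3, edgeR 4.0.16, limma 3.58.1) in 1 fit of all 12 libraries with 4 group means, TMM scaling, the filterByExpr filter on low counts and robust dispersion. P-values were adjusted by the Benjamini-Hochberg method over the 19416 genes that passed the filter, with a threshold of 0.05. Here log2 fold changes are those of the fit, with a standard error (SE) from its quasi-likelihood statistic, and levels are CPM (counts per 1000000 reads of the TMM-scaled library total) with the standard deviation (SD) of 3 libraries. The comparisons were day 2 against day 0 in each genotype, npf8.4-1 against Col-0 at each day, and the interaction, which is the depletion change in npf8.4-1 minus that in Col-0. For 29 gene lists the members were fixed by name, 697 entries in all, and the 27 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2. The same test was run with an estimated correlation, and fry was run for the direction of each list. Cytosolic ribosomal protein genes were found by their annotated names (199 genes). Process names in the reference genome annotation were tested for over-representation among genes changed by at least 2-fold. The test was a one-sided Fisher's exact test against all tested genes that carry a process name. The groups, comparisons, gene lists, naming rule and most alternatives were set before the data were examined.

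Genes were named by rule. NPF8.4 comes first. The 10 largest increases and 10 largest decreases of each comparison (5 and 5 for depletion in npf8.4-1) needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, and all 3 libraries of one group above all 3 of the other. At most 4 genes without a symbol are named per direction. Up to 4 members per list with the smallest p past the threshold were candidates for examples. For the interaction the rule takes the 10 genes with the smallest adjusted p under 0.05, or, where fewer than 3 pass, the 5 smallest unadjusted p, given as not passing. NIA1, NIA2, NIR1, NRT2.4, NRT2.5, GLYK, HPR1 and ASN1 are always given for depletion in Col-0.

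The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 test (1.42.0), no filter beyond 1 read in the 12 libraries, a filter of at least 1 CPM in every library of one group, a fit of only the groups compared, a replicate block, each library left out in turn, and for lists the estimated correlation and fry. Scaling by library totals alone and leaving out the third day 2 library of both genotypes were added after seeing the data. Replicate libraries were checked for duplicates by a chi-square statistic per gene, and no pair agreed within sampling noise. The fit was tested on simulated data drawn from the real means and library sizes, in which 200 genes were changed by known folds. In the design of the genotype comparison at day 2, 40.3% of genes changed 1.5-fold, 78.8% of genes changed 2-fold and 92.4% of genes changed 4-fold were recovered among 19238 genes. In that run 4 unchanged genes were called. The simulated counts were independent, with 1 mean per gene over all 12 libraries before the change. No depletion response, structure shared between libraries or correlation between genes entered.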

Results

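Young leaves of Arabidopsis thaliana were profiled by RNA sequencing in 4 groups of 3 biological replicates, each a pool of 15 plants. Col-0 and the mutant npf8.4-1 were grown in hydroponics on 5 mM KNO3 for 15 days and harvested then (day 0), or after another 2 days on medium free of nitrogen (day 2). The mutated gene, NPF8.4 (also called PTR4), encodes a tonoplast member of the peptide-transporter branch of the NPF family. The 12 libraries held between 28761674 and 34282716 exon reads, and 19416 genes passed the filter on low counts. Day 2 plants were 2 days older than day 0 plants, and a nitrogen-fed group of that age was not analysed here, so depletion and age are measured together. The first principal component carried 75.6% of the variance of log2 CPM and separated the days. The third library of each day 2 group lay closest to day 0 on it, at 49.7 in Col-0 and 51.4 in npf8.4-1, against 66.4 to 82.9 in the other 4 day 2 libraries. The second component carried 5.8% and separated the genotypes, with the 6 Col-0 libraries at 9.8 to 37.3 and the 6 npf8.4-1 libraries at −23.4 to −9.4.

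NPF8.4 (AT2G02020, chromosome 2, 478977 to 481185) had low read counts in every npf8.4-1 library. At day 0 its reads were 250, 231 and 174 in Col-0 and 25, 10 and 10 in npf8.4-1. At day 2 they were 568, 479 and 342 in Col-0 and 22, 47 and 22 in npf8.4-1. NPF8.4 was therefore lower in the mutant by a log2 fold change of −3.74 at day 0 (SE 0.34, edgeR adjusted p = 0.000461) and −4.11 at day 2 (SE 0.31, edgeR adjusted p = 6.35e-05), in 3 of 3 libraries each time. Its transcript rose on depletion in Col-0, from 6.71 ± 1.38 to 15.1 ± 2.86 CPM (SD, n = 3; log2 fold change 1.17, SE 0.26, edgeR adjusted p = 0.00176). The residual transcript in the mutant went from 0.493 ± 0.262 to 0.869 ± 0.388 CPM, a log2 fold change of 0.81 that did not pass (SE 0.41, edgeR adjusted p = 0.101). Without npf8.4-1 day 0 replicate 1 that change was 1.34 and passed, with an adjusted p of 0.0196, and over all alternatives the adjusted p of NPF8.4 there ran from 0.0196 to 0.452. The site of the mutation within the gene is not given in the sources used here. NPF8.3 is a close paralog, so a few of these reads are uncertain.

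**Figure D1:**
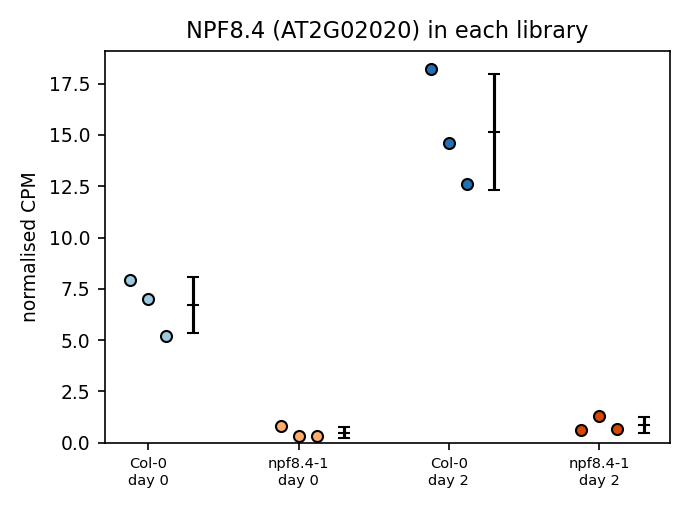
Normalised counts (CPM, vertical axis) of NPF8.4 in each library of the 4 groups (points), with the mean and SD of 3 libraries beside them. The npf8.4-1 libraries lie near 0 at both days, and the Col-0 mean is 6.71 CPM at day 0 and 15.1 CPM at day 2.

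The depletion comparison in Col-0 asked how leaf transcripts differ after nitrate-grown plants spend 2 days without nitrogen. All 17 cell division genes, 177 of 183 cytosolic ribosomal protein genes and the nitrate-induced regulators BT2 and LBD39 fell. Genes of glucosinolate synthesis (19 of 20) and of the photosystems (31 of 39) rose, as did the glutamine synthetase genes GLN1;1 and GLN1;4. In total 5753 genes were higher and 5906 lower at day 2 among 19416 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p), and 4430 of these changed at least 2-fold. An unadjusted p under 0.05 was reached by 12419 genes, where chance gives 971. Camera put 18 of the 27 lists tested past its threshold, 15 higher and 3 lower, but none with an estimated correlation, where the smallest adjusted p = 0.395 with an estimated correlation. The groups are therefore described by their single genes.

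Among genes with the largest changes in Col-0, LURP1, a gene induced in resistance to downy mildew, rose from 0.124 ± 0.107 to 120 ± 31.1 CPM (SD, n = 3; log2 fold change 9.90, SE 0.77). AHP4, a phosphotransfer protein of cytokinin signalling, rose from 0.144 to 22.1 CPM (log2 fold change 7.24, SE 0.45). The beta-glucosidase gene BGLU11 (7.2, SE 0.81), the pathogen- and clock-controlled gene PCC1 (6.34, SE 1.16) and the ankyrin protein gene ANK, AT5G54610 (6.06, SE 0.53) rose as well. A TRAF-like gene, AT4G01390, had 1 read in the day 0 libraries and a ratio of 1330 (95% counting interval 238 to 52500). A rumi-like glycosyltransferase gene, AT3G61280, had 3 reads at day 0 and a ratio of 177 (60.3 to 863). The largest decrease under the naming rule was that of BT2, a nitrate-induced BTB and TAZ domain scaffold protein, from 90.0 ± 30.7 to 3.35 ± 1.25 CPM (log2 fold change −4.76, SE 0.36). LBD39, a nitrate-induced repressor of anthocyanin synthesis, fell from 11.3 to 0.763 CPM (−3.90, SE 0.27). Other decreases were those of a glutaredoxin gene, AT3G21460 (−3.74, SE 0.35), of the embryo-defective genes EMB3120 (−3.41, SE 0.28) and EMB2729 (−3.12, SE 0.29), and of a ribosomal protein L10 gene, AT2G40010 (−3.17, SE 0.21). The largest edgeR adjusted p among these genes was 0.00138, for PCC1.

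Within nitrogen transport and assimilation, all 5 NPF8 peptide transporters rose in Col-0 (list median 1.02), among them NPF8.1 by a log2 fold change of 1.15 (SE 0.14) and NPF8.3 by 0.45 (SE 0.07). Of 18 nitrate transport genes, 13 rose and 2 fell. CLC-A, the nitrate/proton exchanger of the tonoplast, fell (−2.05, SE 0.14), while the phloem nitrate transporter NPF2.13 (1.76, SE 0.17) and the dual-affinity transporter NPF6.3 (1.68, SE 0.17) rose. NRT2.5, a high-affinity transporter induced by starvation, rose from 0.134 to 3.45 ± 3.18 CPM (4.66, SE 0.70), and NRT2.4 lay below the filter on low counts. The nitrate response list was mixed, with 4 genes higher, 9 lower and 13 not passing among 26 (median −0.04, mean −1.66). Its kinase CIPK3 fell (−1.29, SE 0.12), and the glutaredoxin gene GRXS8 fell at least 58.1-fold, from 187 reads to 0, although its close paralogs make that count uncertain. Nitrate and nitrite reduction genes did not pass. NIA1 was at 169 ± 35.8 and 156 ± 53.9 CPM (log2 fold change −0.11, edgeR adjusted p = 0.721), NIA2 at 709 ± 130 and 761 ± 168 CPM (0.10, adjusted p = 0.647), and NIR1 at 262 ± 31.3 and 288 ± 76.6 CPM (0.14, adjusted p = 0.506). The sign of these turned without 1 library. NIA1 came to 0.01 without Col-0 day 0 replicate 2 and to 0.09 without Col-0 day 2 replicate 2. NIA2 came to −0.04 without Col-0 day 0 replicate 3 and to −0.04 without Col-0 day 2 replicate 1, and NIR1 to −0.06 without the latter. In ammonium and amide metabolism 8 of 18 genes rose and 4 fell (median 0.24). The cytosolic glutamine synthetase GLN1;1 rose from 36.4 ± 1.55 to 239 ± 23.2 CPM (2.72, SE 0.10, edgeR adjusted p = 9.66e-09). GLN1;4 (2.07, SE 0.11) and the ammonium transporters AMT1;2 (2.4, SE 0.18) and AMT1;1 (1.53, SE 0.11) also rose, and the asparagine synthetase ASN1 fell (−2.23, SE 0.53, adjusted p = 0.0043).

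In carbon metabolism, 31 of 39 photosystem and antenna genes rose in Col-0 and 8 did not pass (median 0.49), with PSBQ2 at 0.78 (SE 0.12) and the antenna protein gene LHCB4.3 at 1.68 (SE 0.24). Photorespiration genes rose in 15 of 28 cases and fell in 1 (median 0.35). The glycolate transporter BASS6 (2.08, SE 0.12), the glycine decarboxylase subunit GLDP1 (1.00, SE 0.11) and the hydroxypyruvate reductase HPR1 (0.53, SE 0.10) were among those that rose. GLYK, the glycerate kinase of that pathway, did not pass (0.04, edgeR adjusted p = 0.748; −0.03 without Col-0 day 0 replicate 3). Of the 6 genes of the phosphorylated serine pathway, PGDH2 rose (2.16, SE 0.13) and 3 fell, among them PGDH1 (−1.04, SE 0.15). That list had a median of −0.23 and a mean of −0.08, and fry gave it the opposite sign. In the Calvin-Benson cycle 2 of 20 genes rose, 2 fell and 16 did not pass (median 0.00, mean −0.10). PRK, 1 of the 2 that rose (0.30, edgeR adjusted p = 0.0188), lost its call without Col-0 day 0 replicate 2 (0.0596) or 3 (0.0792) and in a fit of only the 2 groups. RBCS1B fell (−1.19, SE 0.17), although reads of RBCS paralogs are hard to separate, and CP12-2 rose (0.72, SE 0.11). Starch synthesis had 10 of 16 genes higher and 6 not passing (median 0.34), with the granule-bound starch synthase GBSS1 at 1.85 (SE 0.16). Starch degradation had 11 of 15 genes higher and 4 not passing (median 0.54), with the glucan phosphatase SEX4 at 1.48 (SE 0.10). In the low energy list 4 of 22 genes rose and 8 fell (median −0.17). The proline dehydrogenase PRODH1 (−2.05, SE 0.22) and the raffinose synthase family gene DIN10 (−2.58, SE 0.45) were among the decreases. Of the genes named here that passed, DIN10 had, after PRK, the largest edgeR adjusted p, 0.000643.

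The pigment, senescence and nutrient lists gave these counts of single genes in Col-0. Flavonoid and anthocyanin genes rose in 15 of 29 cases and fell in 2 (median 0.51), with the MYB regulators PAP1 (1.81, SE 0.21) and MYB90, also called PAP2, AT1G66390 (5.38, SE 0.49). Of 16 senescence and chlorophyll breakdown genes 12 rose and 4 did not pass (median 0.85), including the lipase-like gene SAG101 (1.15, SE 0.11) and pheophytinase, PPH (0.85, SE 0.11). Autophagy genes rose in 12 of 17 cases (median 0.52), led by ATG8A (1.34, SE 0.12) and ATG8I (1.01, SE 0.09). Phosphate starvation genes rose in 6 of 11 cases and fell in 2 (median 0.61), with the galactolipid synthase MGD2 at 1.77 (SE 0.18). Sulfur starvation genes fell in 8 of 11 cases and rose in 1 (median −1.25), and 9 fell when p was adjusted over the list alone. SDI1, a repressor of glucosinolate synthesis, had the log2 fold change −3.75 (SE 0.51). Glucosinolate genes rose in 19 of 20 cases (median 1.99), among them CYP79F1, which makes aliphatic aldoximes, from 17.9 ± 1.53 to 174 ± 33.2 CPM (3.28, SE 0.23), and CYP83A1 (2.02, SE 0.15). The largest edgeR adjusted p in these groups' examples was 4.26e-05, for SDI1.

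The hormone, stress and clock lists gave these counts in Col-0. All 10 salicylate response genes rose (median 2.4), including the immune regulator PAD4, from 6.73 ± 1.96 to 38.0 ± 8.37 CPM (2.5, SE 0.22), and NIMIN1 (3.08, SE 0.31). Jasmonate genes rose in 9 of 13 cases and fell in 1 (median 1.19), and 10 rose when adjusted over the list alone, with the synthesis genes AOS at 1.19 (SE 0.15) and OPR3 at 1.48 (SE 0.24). Abscisic acid and cold genes rose in 14 of 16 cases and fell in 1 (median 1.33), with the transcription factor ABF3 at 1.87 (SE 0.11) and the dehydrin RAB18 at 2.24 (SE 0.18). Genes of touch and handling rose in 9 of 13 cases beside these (median 1.01), for example WRKY33 (1.72, SE 0.38) and ZAT10 (1.45, SE 0.28). The mean of that list was 5.80, 5.72 and 4.87 log2 CPM in the Col-0 day 0 libraries and 6.52, 6.51 and 6.45 in those of day 2. In the cytokinin list 3 of 14 genes rose and 5 fell (median −0.02). The response regulators ARR6 (−3.28, SE 0.42) and ARR4 (−1.43, SE 0.12) fell and the cytokinin oxidase CKX1 rose (3.37, SE 0.48). Of 18 circadian clock genes 5 rose and 2 fell (median 0.09), and 4 rose when adjusted over the list alone. ELF4 rose (1.92, SE 0.36) and ELF3 fell (−1.11, SE 0.24). The largest edgeR adjusted p among genes named here was 0.00278, for WRKY33.

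Cell division and ribosomal protein genes fell in Col-0. All 17 cell division genes were lower (median −1.57), with the replication clamp PCNA2 at −1.64 (SE 0.15) and the helicase subunit MCM2 at −1.57 (SE 0.17). Of 183 cytosolic ribosomal protein genes 177 fell and 1 rose (median −1.87), with the L36e gene AT2G37600 going from 97.6 ± 3.85 to 18.0 ± 2.56 CPM (−2.44, SE 0.14). Among cell type markers, vascular genes rose in 7 of 11 cases, and 8 when adjusted over the list alone (median 0.29), among them the sugar exporter SWEET12 (2.44, SE 0.23) and the phloem sucrose loader SUC2 (1.32, SE 0.17). Stomatal markers rose in 3 of 11 cases and fell in 6 (median −0.22). The stomatal lineage genes TMM (−1.24, SE 0.13) and BASL (−1.73, SE 0.24) fell and the guard cell channels SLAC1 (1.29, SE 0.15) and KAT1 (0.97, SE 0.13) rose. Only 3 of the root markers passed the filter, and the one that changed, PRP3, fell at least 5.59-fold, from 18 reads to 0 (list median 0.09, mean −1.79). Of 3 meristem and flower markers SEP1 rose (0.95, SE 0.24) and AG rose (0.95, SE 0.36, edgeR adjusted p = 0.0377), with a list median of 0.95. The AG call ended without Col-0 day 0 replicate 1 (adjusted p = 0.12) or 3 (0.0811), and without Col-0 day 2 replicate 2 (0.133) or 3 (0.0543), and over all alternatives its adjusted p ran from 0.00659 to 0.133. Of the other genes named here PRP3 had the largest edgeR adjusted p, 0.00459. For every list not given a count over the list alone, that count equalled the one over all genes.

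Depletion in npf8.4-1 lowered cell division and ribosomal protein genes and raised glucosinolate genes. In the mutant 6303 genes were higher and 6141 lower at day 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p), 5104 of them by at least 2-fold. AT1G76960, of unknown function, rose at least 488-fold, from 0 reads to 1688, the nudix hydrolase gene NUDT24 at least 190-fold, and the galactinol synthase gene GolS2 at least 176-fold. AT4G01390 had a ratio of 1570 (95% counting interval 281 to 62000) and AHP4 rose by a log2 fold change of 7.66 (SE 0.47). BT2 fell from 13.1 ± 3.48 to 0.0395 ± 0.0459 CPM (−8.27, SE 0.65), LBD39 fell (−5.15, SE 0.32) and the methionine sulfoxide reductase gene MSRB9 fell (−3.73, SE 0.35). By list, 4 of 5 NPF8 genes rose, led by NPF8.2 (1.59, SE 0.25). Of the nitrate transport genes 12 rose and 2 fell, with CLC-A at −1.80 (SE 0.14). In the nitrate response list 4 rose and 17 of 26 fell (median −0.80). Ammonium and amide genes rose in 10 cases and fell in 5, with GLN1;1 at 2.59 (SE 0.10). All 20 glucosinolate genes rose (median 2.42), for example the sulfotransferase gene SOT18 (1.90, SE 0.10). Salicylate genes rose in 8 of 10 cases (median 0.97), with PAD4 at 1.18 and WRKY70 at 2.01. All 17 cell division genes fell (median −1.78), as did 178 of 183 ribosomal protein genes, with 2 higher (median −2.08). Of the genes named here NUDT24 had the largest edgeR adjusted p, 0.00144.

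The other lists in npf8.4-1 gave these counts by the edgeR test. Photosystem genes rose in 31 cases and fell in 1 and photorespiration genes in 18 and 1. Starch synthesis genes rose in 9 of 16 cases and starch degradation genes in 9 of 15. Autophagy genes rose in 15 of 17 cases, with ATG8A at 1.64 (SE 0.12). Flavonoid genes rose in 16 and fell in 2, senescence genes rose in 10 of 16 and vascular markers in 9 of 11. Phosphate starvation genes rose in 7 and fell in 1, or 9 and 1 when adjusted over the list alone. Abscisic acid and cold genes rose in 11 of 16, or 14 over the list alone, and jasmonate genes rose in 6 and fell in 1, or 5 and 1. Sulfur starvation genes fell in 5 of 11 cases, among them SDI2 (−1.84, SE 0.37). Touch and handling genes rose in 2 and fell in 2 of 13 cases, or 2 and 1 over the list alone (median 0.21), with TCH4 at −1.26 (edgeR adjusted p = 0.0123). TCH2 (−0.38, adjusted p = 0.0332) kept its call in 1 of 6 refits without 1 library (adjusted p up to 0.131), and ERF5 (adjusted p = 0.0164) in 4 of 6 (up to 0.0592). Cytokinin genes rose in 4 and fell in 4, and phosphorylated serine pathway genes in 1 and 3, of which PSAT1 kept its call in 4 of 6 such refits (adjusted p up to 0.074). Of the meristem markers 2 of 3 rose, SEP1 only in 4 of 6 such refits (0.71, adjusted p = 0.0171 and up to 0.103), and 1 of 3 root markers fell. Median and mean differed in sign for the clock list (9 rose, 3 fell; 0.36 and −0.05), the stomatal list (4 rose, 4 fell; 0.09 and −0.06) and the low energy list (7 rose, 6 fell; 0.02 and −0.55). The Calvin-Benson list (3 rose, 4 fell, or 2 and 2 over the list alone) had a median of −0.01 and a mean of −0.04, while camera gave it the opposite sign. Camera put 16 lists past its threshold, 13 higher and 3 lower, and none with an estimated correlation, where the smallest adjusted p = 0.431 with an estimated correlation.

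**Figure D2:**
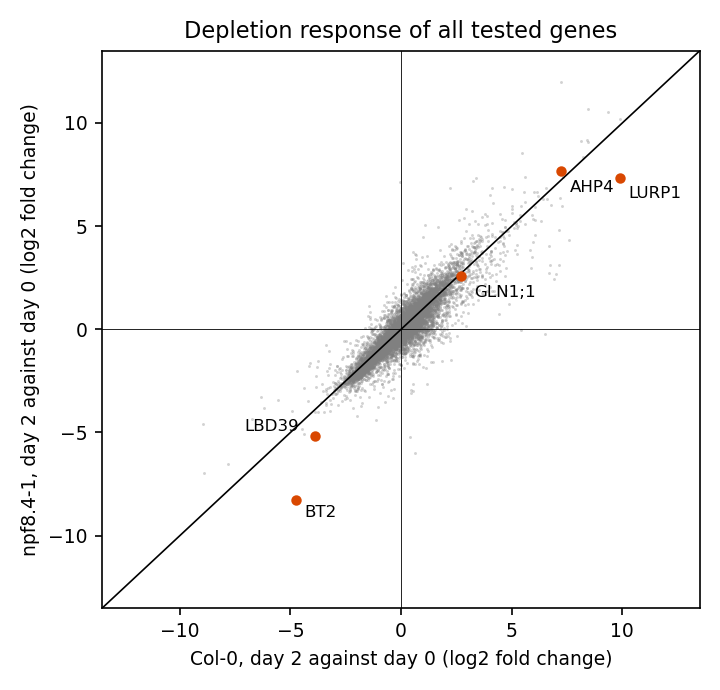
Log2 fold change from day 0 to day 2 in Col-0 (horizontal axis) and in npf8.4-1 (vertical axis) for each tested gene (grey points), with 5 genes in orange and the line of equal change. Most genes lie near the line (Pearson r 0.907 across genes), and BT2 lies below it, at −4.76 in Col-0 and −8.27 in npf8.4-1. The interaction of BT2, which compares these changes, did not pass (edgeR adjusted p = 0.317). Its value in npf8.4-1 rests on 1, 0 and 3 reads in the day 2 libraries.

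The depletion responses of the genotypes were close. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.907 and a Spearman rho of 0.898, with a slope of 1.08 for npf8.4-1 on Col-0. A total of 4863 genes were higher at day 2 in both genotypes, where independent lists would share 1868, and 5252 were lower in both, where independent lists would share 1868. Only 25 genes passed in opposite directions.

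The comparison of npf8.4-1 with Col-0 at day 0 asked what the mutation changes in plants supplied with nitrate. Transcripts of BT2, a gene of both the nitrate response and the low energy list, of the low energy gene TPS11 and of the cytosolic fructose-1,6-bisphosphatase gene FBP were lower in the mutant, and of the fixed lists only the nitrate response, low energy and NPF8 lists held a gene that passed by edgeR. In all, 6 genes were higher and 23 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p), with 1450 at an unadjusted p under 0.05, where chance gives 971. DESeq2 called 109 higher and 123 lower, and a replicate block in the edgeR fit gave 47 and 126. Scaling by library totals alone, an alternative added after seeing the data, gave 3 and 23. Both counts moved with single libraries, to 1 and 11 without Col-0 day 0 replicate 1, to 1 and 11 without its replicate 2, and to 2 and 28 without its replicate 3. They were 3 and 10 without npf8.4-1 day 0 replicate 2 and 2 and 15 without its replicate 3. Besides NPF8.4, 6 named genes kept their call without any one library. FBP (AT1G43670, chromosome 1, 16467298 to 16470500), an enzyme of sucrose synthesis, fell from 240 ± 19.8 to 88.0 ± 3.27 CPM (SD, n = 3; log2 fold change −1.45, SE 0.09, edgeR adjusted p = 2.66e-06). MAF5, a flowering repressor of the FLC family, was lower (−1.45, SE 0.19, adjusted p = 0.00612), as was the alpha/beta hydrolase gene AT2G44970 (−1.13, SE 0.12, adjusted p = 0.000912). Of 2 pseudogenes on chromosome 5, AT5G32678 was at least 907-fold higher, with 2502 reads against 0, and AT5G35935 was lower (−5.52, SE 0.27). AT1G75945, of unknown function, had 1 read in npf8.4-1 against 569 in Col-0, a ratio of 523 (95% counting interval 93.5 to 20700).

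BT2 was lower in npf8.4-1 at day 0 (90.0 ± 30.7 and 13.1 ± 3.48 CPM; log2 fold change −2.78, SE 0.32, edgeR adjusted p = 0.00612). Its call ended without npf8.4-1 day 0 replicate 1 (adjusted p = 0.0551) or 2 (0.0574) and in a fit of the 2 groups alone (0.0985), the highest value among its alternatives, of which DESeq2 gave the lowest, 3.6e-16. Other named genes were AOX1A, an alternative oxidase (0.46, adjusted p = 0.0459), and TPS11, a trehalose phosphate synthase family gene (−1.11, 0.0459). ACBP3, an acyl-CoA-binding protein (−1.01, 0.0156), and MEE14 (−0.96, 0.0459) were named as well. In refits without 1 library AOX1A and MEE14 kept their call in 1 of 6 (adjusted p up to 0.232 and 0.245). TPS11 and ACBP3 kept theirs in 2 of 6 (adjusted p up to 0.245 and 0.144). Among 15 named genes, 7 calls ended without Col-0 day 0 replicate 1 (adjusted p 0.0928 to 0.195), 7 without replicate 2 (0.0984 to 0.269) and 4 without replicate 3 (0.0753 to 0.103). Leaving out npf8.4-1 day 0 replicate 1, 2 or 3 ended 5 (0.0551 to 0.113), 7 (0.0574 to 0.179) and 5 (0.0675 to 0.232) calls. Camera put 12 lists past its threshold at day 0, 5 higher and 7 lower, and 6 without Col-0 day 0 replicate 1, but none with an estimated correlation, where the smallest adjusted p = 0.176 with an estimated correlation. The nitrate response list had a median of −0.58, with 1 gene lower over all genes and 11 of 26 lower when adjusted over the list alone (camera adjusted p = 3.14e-15, and adjusted p = 0.176 with an estimated correlation). The low energy list had a median of −0.51, with BT2 and TPS11 lower, or 10 of 22 over the list alone (camera adjusted p = 7.88e-13, and adjusted p = 0.176 with an estimated correlation). Jasmonate genes had a median of 0.78 with 5 of 13 higher over the list alone but not over all genes (camera adjusted p = 7.23e-05, adjusted p = 0.699 with an estimated correlation, and camera 0.121 without npf8.4-1 day 0 replicate 1, in a range of 1.1e-07 to 0.699 over the alternatives). Beside them, touch and handling genes had a median of 0.39 (camera adjusted p = 0.000717, and adjusted p = 0.699 with an estimated correlation). That call ended without Col-0 day 0 replicate 3 (0.27; 2.58e-06 to 0.699 over the alternatives), the library with the lowest mean of the list, 4.87 log2 CPM.

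At day 2 the same comparison asked what the mutation changes in plants without nitrogen. In npf8.4-1, 12 of 26 nitrate response genes were lower, among them the nitrate reductase gene NIA2, the nitrite reductase gene NIR1 and the regulator HHO3, and so were 2 of 10 salicylate response genes, while 3 of 20 glucosinolate genes were higher. In refits without 1 library NIA2 and NIR1 kept their call in 5 of 6, and the salicylate and glucosinolate genes other than MYB34 in fewer. The edgeR quasi-likelihood test called 94 genes higher and 185 lower (Benjamini-Hochberg adjusted p), 132 of them by at least 2-fold, and 2462 genes reached an unadjusted p under 0.05. DESeq2 called 259 higher and 525 lower, a replicate block in the edgeR fit 260 and 355, and a fit of the 6 day 2 libraries alone 31 and 99. HHO3, a nitrate-induced GARP repressor of starvation genes, was at 126 ± 21.3 CPM in Col-0 and 33.3 ± 8.26 in npf8.4-1 (SD, n = 3; log2 fold change −1.92, SE 0.18, adjusted p = 0.000558). BT2 was at 3.35 ± 1.25 and 0.0395 ± 0.0459 CPM (−6.29, SE 0.77, adjusted p = 0.0055). MYB34, a regulator of indole glucosinolate synthesis, was higher, at 24 against 11.2 CPM (1.1, SE 0.12, adjusted p = 0.000894). The DREB-type factor gene AT2G44940 was higher (1.72, SE 0.22) and the wall-associated kinase-like gene WAKL2 lower (−3.00, SE 0.39). AT5G32678 was at least 1200-fold higher, with 4105 reads against 0, and AT5G35935 was lower (−4.39, SE 0.25). These 7 genes and NPF8.4 kept their call without any one library. FBP was lower as at day 0, at 330 against 125 CPM (−1.40, adjusted p = 3.88e-06); it was singled out after its values were seen. At both days 3 genes were higher and 13 lower, where independent lists would share 0.03 and 0.22, and 203 of the 279 genes called at day 2 had the same sign at day 0. Across all tested genes the 2 genotype comparisons had a Pearson r of 0.239 and a Spearman rho of 0.023.

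**Figure D3:**
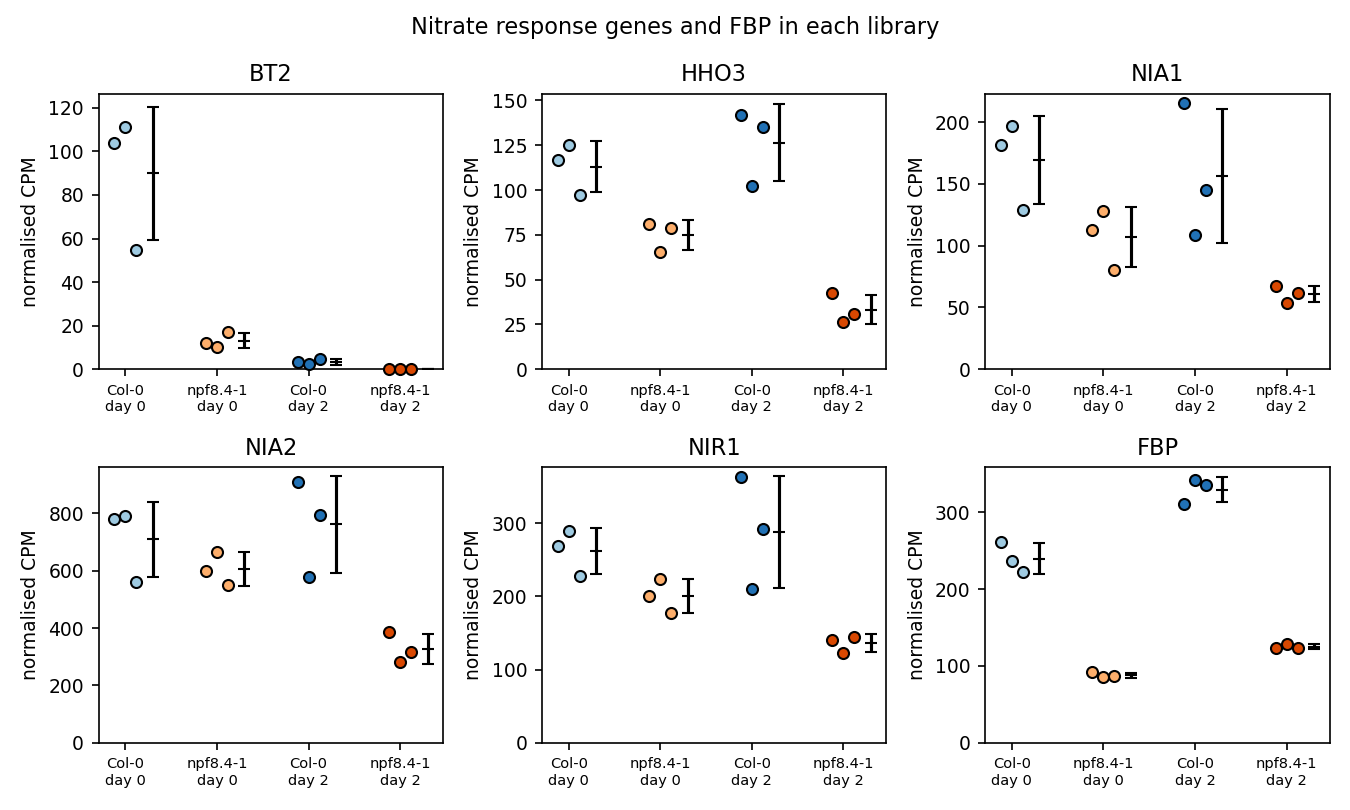
Normalised counts (CPM, vertical axes) of 5 nitrate response genes and of FBP in each library of the 4 groups (points), with the mean and SD of 3 libraries beside them. HHO3 has means of 126 CPM in Col-0 and 33.3 CPM in npf8.4-1 at day 2, and FBP is lower in the mutant at both days.

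Camera put 9 lists past its threshold at day 2, 4 higher and 5 lower, but none with an estimated correlation, where the smallest adjusted p = 0.504 with an estimated correlation. By list, 12 of 26 nitrate response genes were lower, or 13 when adjusted over the list alone (median −0.51; camera adjusted p = 1.77e-12, and adjusted p = 0.504 with an estimated correlation). NIA2 was at 761 ± 168 CPM in Col-0 and 327 ± 53.2 in npf8.4-1 (−1.22, SE 0.18, edgeR adjusted p = 0.00899), and NIR1 at 288 ± 76.6 and 136 ± 11.7 CPM (−1.08, SE 0.17, adjusted p = 0.0125). Of the 18 circadian clock genes 1 was higher over the list alone but not over all genes (camera adjusted p = 0.692). Their median absolute log2 fold change between the genotypes was 0.314 at day 2, larger than in all but 5 of 10000 random lists matched on expression, which take no account of correlation between genes, and 0.115 at day 0. Salicylate genes had a median of −0.56, with 2 of 10 lower, or 6 over the list alone (camera adjusted p = 1e-05, and adjusted p = 0.504 with an estimated correlation). PAD4 was at 38.0 CPM in Col-0 and 18.7 in npf8.4-1 (−1.02, SE 0.21, adjusted p = 0.0344) and its partner EDS1 was lower (−0.56, adjusted p = 0.0352). Without 1 library PAD4 kept its call in 2 of 6 refits and EDS1 in 1 of 6 (edgeR adjusted p up to 0.167 and 0.136). Touch and handling genes, markers of how plants were handled, were lower too (median −0.44), with 1 of 13 called, or 4 lower and 1 higher over the list alone (camera adjusted p = 0.000549, and adjusted p = 0.504 with an estimated correlation). Their mean was 6.52, 6.51 and 6.45 log2 CPM in Col-0 and 6.15, 5.88 and 5.83 in npf8.4-1. Glucosinolate genes had a median of 0.45, with 3 of 20 higher, or 7 higher and 1 lower over the list alone (camera adjusted p = 2.74e-06, and adjusted p = 0.504 with an estimated correlation). SOT18 (0.58) and UGT74B1 (0.46) were among those higher, but kept their call in only 4 and 1 of 6 refits without 1 library (edgeR adjusted p up to 0.101 and 0.178). In the low energy list 4 of 22 genes were lower, or 9 over the list alone (median −0.05, mean −0.76; camera adjusted p = 0.000101, and adjusted p = 0.504 with an estimated correlation), among them TPS8 (−1.22), TPS11 (−1.20) and BZIP1 (−1.02). Singly, PAP1 was higher (1.13, SE 0.20, adjusted p = 0.0172), and AMT1;1 (−0.52) and SAG101 (−0.58) were lower. In the cytokinin list, with a median of 0.42, 1 of 14 genes was lower, the oxidase gene CKX4 (−0.80), or 3 higher and 1 lower over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.762 with an estimated correlation). The list's call ended without Col-0 day 2 replicate 3 (0.0765) or npf8.4-1 day 2 replicate 2 (0.107), and CKX4 kept its own in 1 of 6 refits without 1 library (adjusted p up to 0.174). Among the largest changes, BBX29 (1.38, adjusted p = 0.0106) and MYB7 (1.41, 0.0254) were higher, and PP2-B13 (−3.26, 0.00807), CYP81F2, an enzyme of indole glucosinolate modification (−2.80, 0.0344), XTH18 (−3.05, 0.0486) and MYB70 (−2.21, 0.0249) were lower.

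Of 38 named genes at day 2, the calls of 30 ended without npf8.4-1 day 2 replicate 2 (edgeR adjusted p 0.0668 to 0.226), among them NIA2, NIR1, PAD4 and PAP1. Leaving out npf8.4-1 day 2 replicate 1 ended 8 calls (0.0572 to 0.121) and replicate 3 ended 19 (0.0531 to 0.188). Leaving out Col-0 day 2 replicate 1, 2 or 3 ended 6 (0.0538 to 0.106), 12 (0.055 to 0.131) and 11 (0.0503 to 0.178). The totals moved with single libraries as well. Without npf8.4-1 day 2 replicate 2 there were 7 genes higher and 22 lower, without its replicate 1 51 and 150, and without its replicate 3 41 and 47. Without Col-0 day 2 replicate 1 there were 124 and 222, without its replicate 2 38 and 140, and without its replicate 3 21 and 141. Without the third day 2 library of both genotypes 12 genes were higher and 32 lower, 42 of them among the 279; this alternative was added after seeing the data.

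**Figure D4:**
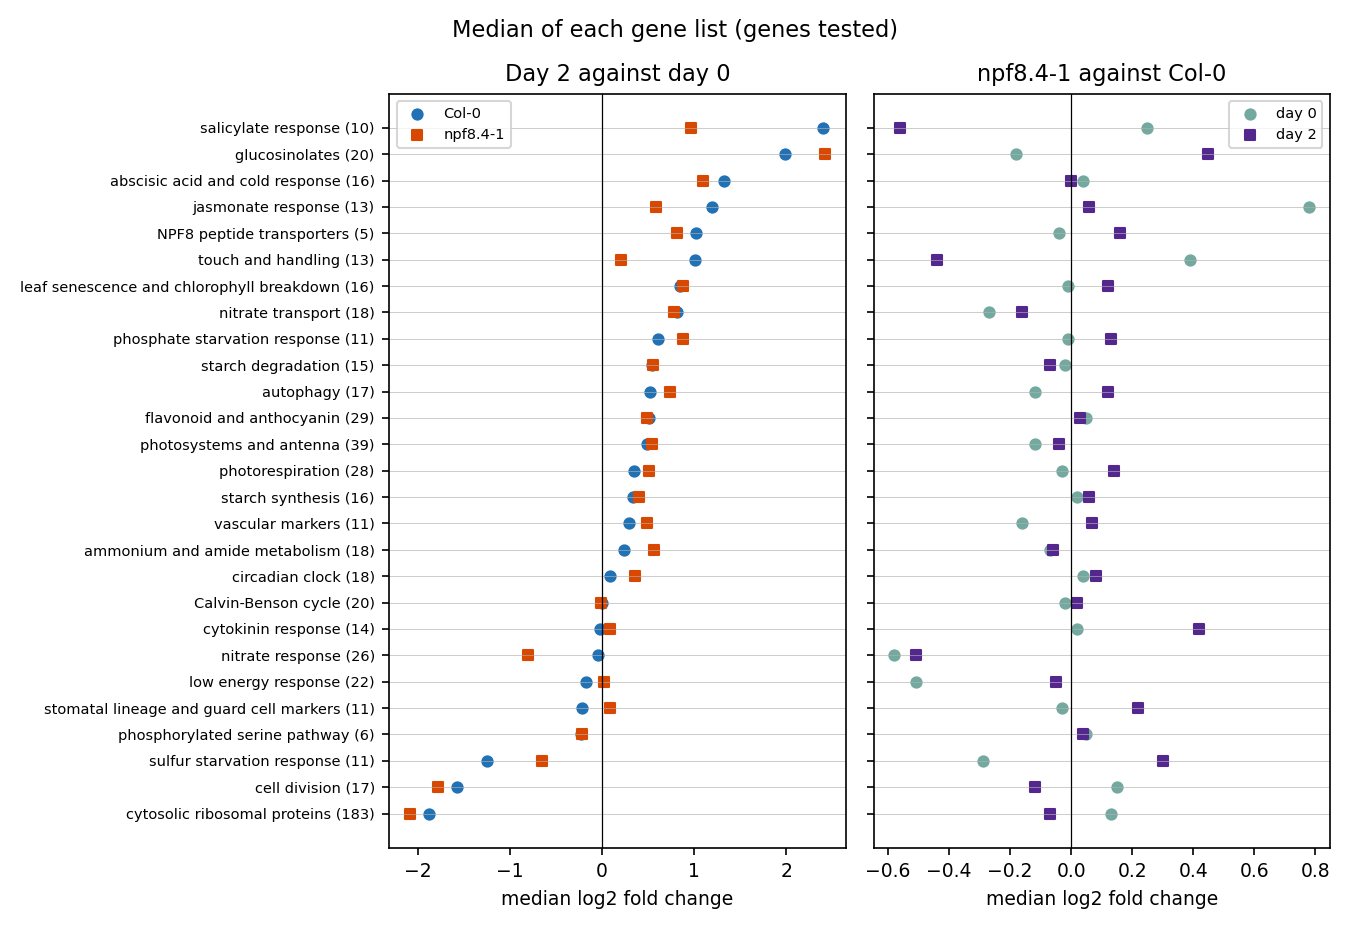
Median log2 fold change of each gene list with at least 5 tested genes (horizontal axes), day 2 against day 0 in each genotype on the left and npf8.4-1 against Col-0 at each day on the right, with the number of genes tested in brackets. Cytosolic ribosomal proteins have the lowest depletion medians, −1.87 in Col-0 and −2.08 in npf8.4-1, and the nitrate response list is lower in the mutant at both days, at −0.58 and −0.51.

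The interaction asked whether the change on depletion differed between the genotypes. No gene passed by the edgeR quasi-likelihood test (0 higher and 0 lower, smallest Benjamini-Hochberg adjusted p = 0.17), 1759 genes had an unadjusted p under 0.05, and DESeq2 called 56 higher and 213 lower. The planned replicate block in the edgeR fit gave 15 higher and 28 lower (smallest edgeR adjusted p = 0.0296). Whether genes differ in this comparison thus depends on the model, and whether the replicate numbers pair the samples is open. NPF8.4 had a log2 fold change of −0.37 (edgeR adjusted p = 0.871), or 0.17 without npf8.4-1 day 0 replicate 1, with an adjusted p of 0.779 to 0.972 over all alternatives. The 5 genes with the smallest p, none of which passed, were AT5G25170 (−1.19), the calcium-dependent kinase gene CPK4 (−1.08), the receptor-like kinase gene AT1G53430 (−0.77), AT5G57887 (0.96) and the amino acid permease gene AAP5 (−1.30). Without Col-0 day 2 replicate 1, 1 gene passed with a positive and 5 with a negative interaction, AT5G25170 (adjusted p = 0.0316) and AAP5 (0.036) among them. Over all alternatives the adjusted p ran from 1.43e-05 by DESeq2 to 0.483 for AT5G25170 and from 9.21e-05 by DESeq2 to 0.499 for AAP5. The median standard error of the interaction was 0.196 on the log2 scale. Camera put 11 lists past its threshold, none with an estimated correlation, where the smallest adjusted p = 0.553 with an estimated correlation. The count was 7 without Col-0 day 0 replicate 1.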

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

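The tests of linkage to NPF8.4, of scaling and of the harvest time, and the splits of 6 libraries, were chosen only after the results were seen. The 11 lists that follow stood out because their depletion change differed between the genotypes by the interaction, tested with camera at its preset correlation. Median interactions are npf8.4-1 minus Col-0 on the log2 scale. Depletion changes were lower in npf8.4-1 for touch and handling (median −0.86, camera adjusted p = 1.24e-07), salicylate response (−0.78, 1.24e-07) and jasmonate response (−0.49, 0.00921). They were also lower for cell division (−0.30, 0.0139) and cytosolic ribosomal proteins (−0.20, 1.24e-07). Changes were higher in npf8.4-1 for glucosinolates (0.59, 1.24e-07), sulfur starvation (0.44, 0.00921), stomatal markers (0.33, 0.0248) and cytokinin response (0.31, 0.0492). Autophagy (0.29, 0.000952) and photorespiration (0.15, 0.0432) were higher as well. No list among them held with an estimated correlation, where the adjusted p ran from 0.553 to 0.836. Adjusted over the list alone, 6 glucosinolate genes had a positive interaction, and 6 salicylate and 2 touch and handling genes a negative one. No gene passed over all genes by edgeR, 1759 had an unadjusted p under 0.05, and DESeq2 called 56 higher and 213 lower. With a replicate block edgeR called 15 higher and 28 lower. In 100 splits of the genotypes within each day, 17, the real one included, gave at least 1759 genes at an unadjusted p under 0.05 (highest other 5266). For the 11 lists, 24 splits, the real one included, gave as many (highest other 16), so chance cannot be excluded for either count. The splits ignored the replicate numbers, which carry some shared structure that may raise the counts of other splits. They therefore do not measure chance alone and cannot decide the question. Which split gave 5266 genes was not recorded, so whether it follows genotype or another structure of the samples is not known.

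By camera the nitrate response list was lower in npf8.4-1 at both days, with medians of −0.58 and −0.51 and 1 and 12 of 26 genes called, but not with an estimated correlation (adjusted p = 0.176 with an estimated correlation at day 0 and adjusted p = 0.504 with an estimated correlation at day 2). Fry, which does not compare a list with other genes, put it lower at day 0 (fry adjusted p = 0.0455) and day 2 (fry adjusted p = 0.0319). Scaling of the libraries is argued against, since the highest median over both days and both other scalings was −0.49. The highest camera adjusted p without any one library was 1.6e-07, but it rests on the preset correlation and cannot decide about a single library. The list means by library do argue against a single library. At day 0 they were 4.12, 4.16 and 3.68 log2 CPM in Col-0 and 3.4, 3.37 and 3.15 in npf8.4-1. At day 2 they were 3.17, 2.69 and 2.85 in Col-0 and 2.24, 2.07 and 2.15 in npf8.4-1. A different time of harvest stays open at day 2, because the clock list's median absolute difference lay at percentile 99.95 of matched random lists there, which take no account of correlation between genes, and is undecided at day 0, at percentile 69.81. The list may also be lower because nitrate supply or storage differs in plants without NPF8.4, which no measurement here tests and which a second allele or a complemented line would separate from other differences of this line.

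At both days 16 genes differed between the genotypes, among them NPF8.4, FBP, BT2, TPS11 and ACBP3. Reads shared with near-identical copies are argued against for the set, because only 1 of the other 15 genes, the long non-coding RNA gene AT3G29644, had a stretch of at least 200 bases at 95% identity elsewhere in the genome. A tract of other DNA linked to NPF8.4 is argued against as well, since 0 of the 15 genes lay within 3 Mb of it. A tract elsewhere in the genome was not tested. On chromosome 3, AT3G29644 (start 11498879; −2.00 at day 0 and −1.75 at day 2) was lower in npf8.4-1. So was a second long non-coding RNA gene, AT3G05955 (start 11586005; −5.19 and −5.51), at only 0.95 CPM in Col-0 at day 0. The large differences of AT5G32678, AT5G35935 and AT1G75945, on other chromosomes, are what differences of sequence elsewhere in the mutant's genome might give. With 1 mutant line, such differences and the loss of NPF8.4 were not separated.

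More genes were called between the genotypes at day 2 (279) than at day 0 (29). A larger spread between replicates at day 0 is argued against, because the mean within-group spread at day 0 was 0.81 of that at day 2. Whether npf8.4-1 day 2 replicate 2 alone accounts for the larger count at day 2 is undecided. Only 29 genes were called without that library. The fold changes of the 279 genes without it had a median ratio of 0.96 to the full values. Those genes were chosen because they passed with that library included, so this ratio cannot decide. A larger effect of the mutation under depletion may account for the count, but the interaction test called 0 genes by edgeR (1759 at an unadjusted p under 0.05). It called 15 higher and 28 lower with a replicate block, and 56 and 213 by DESeq2. In addition, 1 split of the day 2 libraries called more genes than the genotypes did.

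With 3 libraries against 3 there are 10 splits, the real one included, too few for a share under 0.05. Each count of splits as large also includes the real one, so 1 as large means that no other split reached it. For depletion in Col-0 the real split called 11659 genes, with 1 split as large and a highest other of 0, and 18 lists, with 2 as large and a highest other of 18. Depletion in npf8.4-1 gave 12444 genes, with 1 as large and a highest other of 0, and 16 lists, with 2 as large and a highest other of 17. In both depletion comparisons every other split mixes the days, so the depletion change enters the spread within groups. The counts of 0 genes were thus largely fixed in advance and cannot decide about chance. The genotypes at day 0 gave 29 genes, with 1 as large and a highest other of 0, and 12 lists, with 3 as large and a highest other of 14. At day 2 they gave 279 genes, with 2 as large and a highest other of 612, and 9 lists, with 5 as large and a highest other of 15. The split with 612 genes set Col-0 replicate 1 and npf8.4-1 replicates 1 and 2 on one side. Col-0 replicates 2 and 3 and npf8.4-1 replicate 3 were on the other. This points to a structure of the day 2 samples other than genotype, one that parts the libraries numbered 1 from those numbered 3. Deviations of the day 2 libraries correlated at 0.22 between those numbered 1 and at 0.42 between those numbered 3, against −0.44 and −0.27 between the 2 numbers. What the numbers stand for is not known.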

How the results depend on the processing

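Scaling by library totals alone and leaving out the third day 2 library of both genotypes were chosen after seeing the data, and the other alternatives were planned. Every count of genes changed by depletion stayed within 1.5 times its value under all alternatives tried. The correlation of the depletion responses across genes was 0.613 with no filter, where more genes of few reads enter, 0.933 with the stricter filter and 0.924 with only the groups compared in the fit. Its range was 0.875 to 0.903 when 1 library was left out. DESeq2 called more genes between the genotypes, 109 higher and 123 lower at day 0 and 259 and 525 at day 2, and 56 and 213 for the interaction. Library totals gave 3 genes higher and 23 lower at day 0, against 6 and 23. A fit of only the 6 day 2 libraries, with fewer degrees of freedom, called 31 higher and 99 lower, 104 of them shared with the 279, against 94 and 185. Without the third day 2 library of both genotypes 12 were higher and 32 lower. When 1 library was left out, the genes higher at day 0 ran from 1 to 4 and those lower from 10 to 28. The genes higher at day 2 ran from 7 to 124 and those lower from 22 to 222. For the interaction 0 to 1 were higher and 0 to 5 lower. The share of higher calls at day 2, 33.7%, was 13% without Col-0 replicate 3 and 46.6% without npf8.4-1 replicate 3. Fewer samples are part of these changes by construction; what sets one library apart from another, and the cause of the DESeq2 differences, was not tested.

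The replicate block moved the counts between the genotypes from 6 and 23 to 47 and 126 at day 0, from 94 and 185 to 260 and 355 at day 2, and from 0 and 0 to 15 and 28 for the interaction. Among single named genes it ended 4 calls and added 6. Deviations of libraries that share a number had correlations of −0.17 to 0.42. They were 0.07 to 0.36 among libraries numbered 1 and 0.06 to 0.42 among those numbered 3, against −0.44 to −0.08 between the 2 numbers, but −0.17 to 0.02 among those numbered 2. The numbers thus carry some shared structure. Not every library correlated best with its own number and not every pair was over 0.1. Deviations of the 3 libraries of a group cancel around their mean, so a middle library has little deviation left to correlate. Low values at number 2 therefore do not decide against pairing. The main fit had no block, as set before the data were examined, and whether the numbers pair the samples is left open.

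Camera's list counts were 18 and 16 for depletion in Col-0 and npf8.4-1, 12 and 9 for the genotypes at day 0 and day 2, and 11 for the interaction. All 5 were 0 with an estimated correlation; the cause was not tested. With fry, which does not compare a list with other genes, they were 22, 20, 2, 1 and 0. Without 1 library they ran from 6 to 12 at day 0, from 6 to 11 at day 2 and from 7 to 13 for the interaction. Refits of called lists without 1 library kept the call in 403 cases, lost it in 58 and reversed in 1. The reversed list was cytosolic ribosomal proteins between the genotypes at day 2, with a median of −0.07 that ran from −0.23 to 0.02, the last without Col-0 day 2 replicate 3.

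For single named genes, leaving out 1 library kept 1764 results, ended 140 calls, gave 3 new calls and reversed 7 signs, all of values that did not pass. For depletion in Col-0, NIA1 ran from −0.41 to 0.09 (0.01 and 0.09 where it turned, against −0.11), NIA2 from −0.04, reached in 2 refits, to 0.27 (against 0.10), NIR1 from −0.06 to 0.32 (against 0.14), and GLYK had −0.03 as its lowest value (against 0.04). NPF8.4 ran from −0.80 to 0.17 for the interaction (against −0.37). DESeq2 size factors ended 1 call, library totals 12, no filter 5, the stricter filter 1, only the groups compared 26, and leaving out the third day 2 library of both genotypes 27 of 44, while the DESeq2 test added 6. The cause was not tested. Other scalings moved the median of all genes by at most 0.074 on the log2 scale. Depth limits genes of few reads, such as NRT2.4 and NPF8.4 in the mutant. The simulated recovery of 40.3% of 1.5-fold changes at day 2 means that small genotype differences can be missed. That simulation had independent counts without shared structure, so recovery in the real libraries may differ.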

Other observations

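The tests of annotated processes here were chosen only after the main comparisons had been seen. In Col-0, annotated processes of protein synthesis were enriched among the genes that fell; the terms translation and ribosome biogenesis include ribosomal protein genes of the fixed list, which were not removed. Among the genes that fell at least 2-fold, 257 of the 361 annotated to translation were found where chance gives 46.2 (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.1e-152). Ribosome biogenesis gave 81 of 100 genes (12.8 by chance, adjusted p = 5.01e-53) and tRNA aminoacylation 16 of 30 (3.8 by chance, adjusted p = 3.65e-06). Processes of chromatin and cytoskeleton were enriched as well, with nucleosome assembly at 27 of 49 genes (6.3 by chance, adjusted p = 8.65e-11), DNA replication at 23 of 40 (5.1, adjusted p = 9.95e-10) and microtubule-based movement at 18 of 45 (5.8, adjusted p = 0.000105). Mitochondrial protein targeting had 7 of 11 genes (1.4, adjusted p = 0.00204). In npf8.4-1, 276 of the 361 translation genes fell (adjusted p = 3.43e-159), with 19 of 30 tRNA aminoacylation genes (4.5, adjusted p = 6.44e-08) and 8 of 11 genes of lysine synthesis (1.6, adjusted p = 0.000535).

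Genes that rose at least 2-fold on depletion in Col-0 were enriched for defense response, with 71 of 226 genes (23.7 by chance, adjusted p = 6.15e-16), for innate immune response, with 30 of 77 (8.1, adjusted p = 2.84e-09), and for water deprivation, with 22 of 67 (7, adjusted p = 3.06e-05). Drug transmembrane transport, which holds mostly MATE transporters, had 16 of 44 genes (4.6, adjusted p = 0.000195). In npf8.4-1 defense response had 53 of 226 genes (27.1, adjusted p = 0.000136) and drug transmembrane transport 18 of 44 (5.3, adjusted p = 0.000136). Toxin catabolism, which holds glutathione transferases, had 7 of 13 genes (1.6, adjusted p = 0.00776) in npf8.4-1. Genes are not independent of each other in this test, so these p-values are too small. No process passed among genes called between the genotypes at day 2.

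Some library values belong to no comparison. Col-0 day 2 replicate 3 had 11.05% of its reads in its 10 most abundant genes, against 7.89% to 9.78% in the other 11 libraries, and 0.171% of reads on chloroplast genes, against at most 0.112% elsewhere. The median within-group SD of log2 CPM was 0.121 in Col-0 and 0.147 in npf8.4-1 at day 0, and 0.177 and 0.154 at day 2.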
